A study of Mus musculus with 11 samples.

How the data were processed

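RNA from the thymus of FVB mice was measured on 11 Affymetrix whole-transcript arrays, 1 per sample, from 300 ng of total RNA each, per the labels' protocols. The samples fall into 4 groups by their titles: normal thymocytes (n = 3), wild-type lymphomas (n = 3), Dnmt3b-deficient lymphomas (n = 3) and pre-tumor Dnmt3b-deficient thymocytes (n = 2). The labels call the members of each group biological replicates. Dnmt3b is an enzyme that places new methyl groups on DNA. The mice carry tetracycline-controlled transgenes: EμSR-tTA, a transcriptional activator made in blood cells, switches on Teto-MYC (the oncogene) and, where present, Teto-Cre, a recombinase that removes DNA between loxP sites and also turns on an EGFP reporter. Normal thymocytes carry the activator, the Cre transgene and the reporter, with intact Dnmt3b and no MYC transgene. Wild-type lymphomas carry MYC and a floxed Dnmt3b gene without Cre, so that the gene stays intact. Dnmt3b-deficient lymphomas and pre-tumor thymocytes carry MYC and Cre, and are labelled as lacking Dnmt3b. Normal and pre-tumor thymocytes were taken at 24 days of age, and tumors when the disease was apparent. Per the labels' protocols, pre-tumor thymi were sorted for EGFP-positive cells, while tumors went into TRIzol unsorted, so sorting goes with stage. Whether the normal thymocytes were sorted is not clear from the labels. Among the tumors, the Cre transgene goes with the Dnmt3b genotype.

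The deposited values are on a log2 scale, and the submitters' processing notes name Partek and RMA, without versions or an order of steps. The genome build behind the annotation is not given in the sources used here. In the table, no value lies below 3.32, which is log2 of 10, and between 23.6% and 25.7% of the values on each array equal this floor. Of the 35512 probe sets in the table, 5475 sit at the floor on all 11 arrays. A level below the floor cannot be read, so a fold change against a group whose arrays are all at the floor is given as "at least" the value against the floor. Where only some arrays of the lower group are at the floor, the difference given is a lower limit too. Ties at the floor also give some probe sets no spread at all, which weakens the moderation of variances: its prior degrees of freedom were 0.46 over all tested probe sets and 1.94 without those at the floor on every array, beside 7 residual degrees of freedom. Array medians over the whole table lay between 4.55 and 4.62, and no further normalization was applied. Arrays have no read depth, and the number of arrays limits the precision.

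Probe sets were named through the platform annotation. The 6573 probe sets with the lowest ID numbers have no gene in it and were left out as probable controls, a choice inferred from the IDs. This left 28939 probe sets: 21789 with 1 gene symbol, 1621 with several, which are not named, and 5529 with none. The single symbols cover 19938 genes, of which 999 lie on several probe sets. A RefSeq gene table of assembly GRCm38.p6 was used for current symbols, of which 0 had to be updated, and for which genes neighbour each other; none of its coordinates are printed.

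The groups, the lists of genes, the comparisons, their tests and most alternatives were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 4 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), so that all groups share 1 estimate of the spread per probe set. There were 5 comparisons: Dnmt3b-deficient against wild-type lymphomas, each lymphoma against normal thymocytes, pre-tumor Dnmt3b-deficient against normal thymocytes, and Dnmt3b-deficient lymphomas against pre-tumor thymocytes. A probe set counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over the 28939 probe sets. All adjusted p-values of single genes come from limma. Differences are log2 values of the group named first minus the other. The Dnmt3b level in the tumors was also compared by a two-sided exact permutation test.

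The genes named are Dnmt3b, Dnmt1, Dnmt3a, Myc and Ment (on the array under its older symbol Gm128). They were tested in every comparison, though not every value is printed. Also named, per comparison, are the 10 largest rises and 10 largest falls past the threshold with no overlap between the samples of the groups, 1 probe set per gene. Predicted or unnamed genes, small RNA genes and immunoglobulin or T cell receptor segments were left out of this ranking. Where fewer than 5 passed in a direction, the 10 largest differences at an unadjusted p under 0.05 are given as not passing, and all calls of a list of 5 or fewer are named. Up to 4 members past the threshold are named from each list; members named from lists with none past it were chosen after their values were seen.

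There were 23 lists of genes. The pathway lists are DNA methylation machinery, MYC-induced ribosome biogenesis and metabolism, CDK inhibitors, DNA replication and S phase, mitosis, p53 targets, the BCL2 family, the interferon response, the Notch pathway, germline genes, imprinted genes and T cell receptor signalling. Thymocyte stages are covered by early double-negative, double-positive and mature single-positive genes, and other cell types by thymic epithelium, B cells, macrophages and monocytes, dendritic cells, neutrophils, NK and cytotoxic cells, erythroid cells, and stroma and endothelium. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with the probe set of highest mean for each gene and adjustment over the 23 lists, and again with a correlation estimated from the data. Counts of members past the threshold are given over all probe sets and adjusted over the list alone.

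The alternatives were a variance trend, no moderation, array weights, only the 2 groups compared, centring each array on its median, a new quantile normalization, leaving out the dimmest probe sets (a fraction of 0.333), a fold change of at least 2, 1 probe set per gene, the replicate number as a block, and leaving out each replicate in turn, for every comparison, since all groups share 1 estimate of the spread. Leaving out the probe sets at the floor on all arrays and keeping the low-ID probe sets were added after the data had been seen. Each fit was tested on simulated data with the spread of these samples. Of the 28939 probe sets, 100 were changed by 1 and 100 by 2 on the log2 scale. All of these were drawn from probe sets with a mean level above the median. Between the tumor genotypes the fit recovered 49% and 83% of them with 10 false calls, for wild-type lymphoma against normal 50% and 89% with 6, for Dnmt3b-deficient lymphoma against normal 40% and 83% with 3, for pre-tumor against normal 41% and 78% with 14, and for Dnmt3b-deficient lymphoma against pre-tumor thymocytes 35% and 77% with 9. Recovery of probe sets below that median, which include those at the floor, was not measured. With the mitosis list raised, camera called 1 of the 23 lists, the raised one. The simulated genes varied independently, so this check cannot show false list calls that arise when genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.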

Results

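Gene expression was compared between normal thymocytes, thymic lymphomas induced by MYC with intact or with deleted Dnmt3b, and thymocytes of the deleted genotype before tumors appeared, with 3, 3, 3 and 2 mouse samples. The study asks how loss of the DNA methyltransferase Dnmt3b alters gene expression in MYC-induced lymphoma. The first principal component held 56.6% of the variance and set the 3 normal samples (-87.1 to -64.7) apart from the other 8 (10.2 to 45.3). The second held 10.6%. Within groups, arrays correlated with r between 0.968 and 0.985 over probe sets.

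The targeted gene, Dnmt3b, gave similar signals in all 11 samples. Its log2 level was 5.22, 5.31 and 5.30 in normal thymocytes, 5.36, 5.59 and 5.70 in wild-type lymphomas, 5.26, 5.49 and 5.40 in Dnmt3b-deficient lymphomas, and 5.07 and 5.24 in pre-tumor Dnmt3b-deficient thymocytes. Between the tumor genotypes it differed by -0.17 (SE 0.10), which did not pass limma (adjusted p = 0.899) or the two-sided exact permutation test (p = 0.3, where 20 arrangements allow no p below 0.1). Against normal thymocytes the differences were 0.27 in wild-type lymphomas (adjusted p = 0.106, and 0.0367 without wild-type replicate 1), 0.11 in Dnmt3b-deficient lymphomas (0.593) and -0.12 in pre-tumor thymocytes (0.542). Whether the probe set covers the deleted part of the gene is not given in the sources used here, so this level does not check the genotype labels.

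Dnmt1, which maintains methylation at cell division, had a mean log2 level of 9.42 in normal thymocytes, 9.55 in wild-type lymphomas, 9.76 in Dnmt3b-deficient lymphomas and 9.66 in pre-tumor thymocytes. Between the tumor genotypes it differed by 0.21 (SE 0.06), with no overlap between the samples, and did not pass limma (adjusted p = 0.602). It rose against normal in the Dnmt3b-deficient lymphomas by 0.35 (adjusted p = 0.00482). The pre-tumor difference of 0.24 passed narrowly (0.0358) and did not pass without any one of the 5 samples compared: 0.0920, 0.0573 and 0.0765 without normal replicates 1, 2 and 3, and 0.0874 and 0.207 without pre-tumor replicates 1 and 2. It also missed the threshold without wild-type replicate 1 (0.0567) or Dnmt3b-deficient replicate 2 (0.0546), whose spread enters the fit. Further, it missed the threshold after a new quantile normalization (0.140), without probe sets at the floor (0.0621), without the dimmest probe sets (0.127) and with only the 2 groups compared (0.0559). Dnmt3a, the other enzyme for new methylation, ranged widely in wild-type lymphomas (7.20 ± 0.76, SD, n = 3) and passed in no comparison. Its wild-type lymphoma difference from normal of -0.66 (adjusted p = 0.269) passed only without wild-type replicate 3 (0.010), as did its Dnmt3b-deficient lymphoma difference of -0.78 (0.191, and 0.0174 without that replicate). Its difference between the tumor genotypes, -0.12, became 0.31 without wild-type replicate 3 and 0.014 without Dnmt3b-deficient replicate 2.

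The mouse Myc probe set fell in all 3 groups with the MYC transgene, from 7.90 ± 0.20 in normal thymocytes (SD, n = 3) to 5.24 ± 0.40 in wild-type lymphomas (n = 3), 4.62 ± 0.32 in Dnmt3b-deficient lymphomas (n = 3) and 5.87 in pre-tumor thymocytes (n = 2). The adjusted p-values were 0.000728, 0.000266 and 0.00320. Between the tumor genotypes the Myc probe set differed by -0.62 (SE 0.23), which did not pass limma (adjusted p = 0.757). Whether this probe set reads the MYC transgene is not given in the sources used here. Ment (Gm128 on the array), a gene this study follows, had a level of 4.57 ± 0.20 in normal thymocytes, 3.99 ± 0.11 in wild-type lymphomas, 5.13 ± 0.19 in Dnmt3b-deficient lymphomas (SD, n = 3 each) and 5.20 ± 0.01 in pre-tumor thymocytes (n = 2). It fell by 0.58 in wild-type lymphomas against normal (adjusted p = 0.0167, 0.0634 without wild-type replicate 1). It rose by 0.56 in Dnmt3b-deficient lymphomas (0.0190) and by 0.63 in pre-tumor thymocytes (0.0205). The lymphoma rise was not called without normal replicates 1 (0.0646) or 3 (0.0603), without Dnmt3b-deficient replicates 2 (0.0665) or 3 (0.0589), or with only the 2 groups compared (0.0861). The pre-tumor rise was not called without normal replicates 1 (0.0576) or 3 (0.0539), pre-tumor replicates 1 (0.0710) or 2 (0.125), or with only the 2 groups (0.0898).

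**Figure D1:**
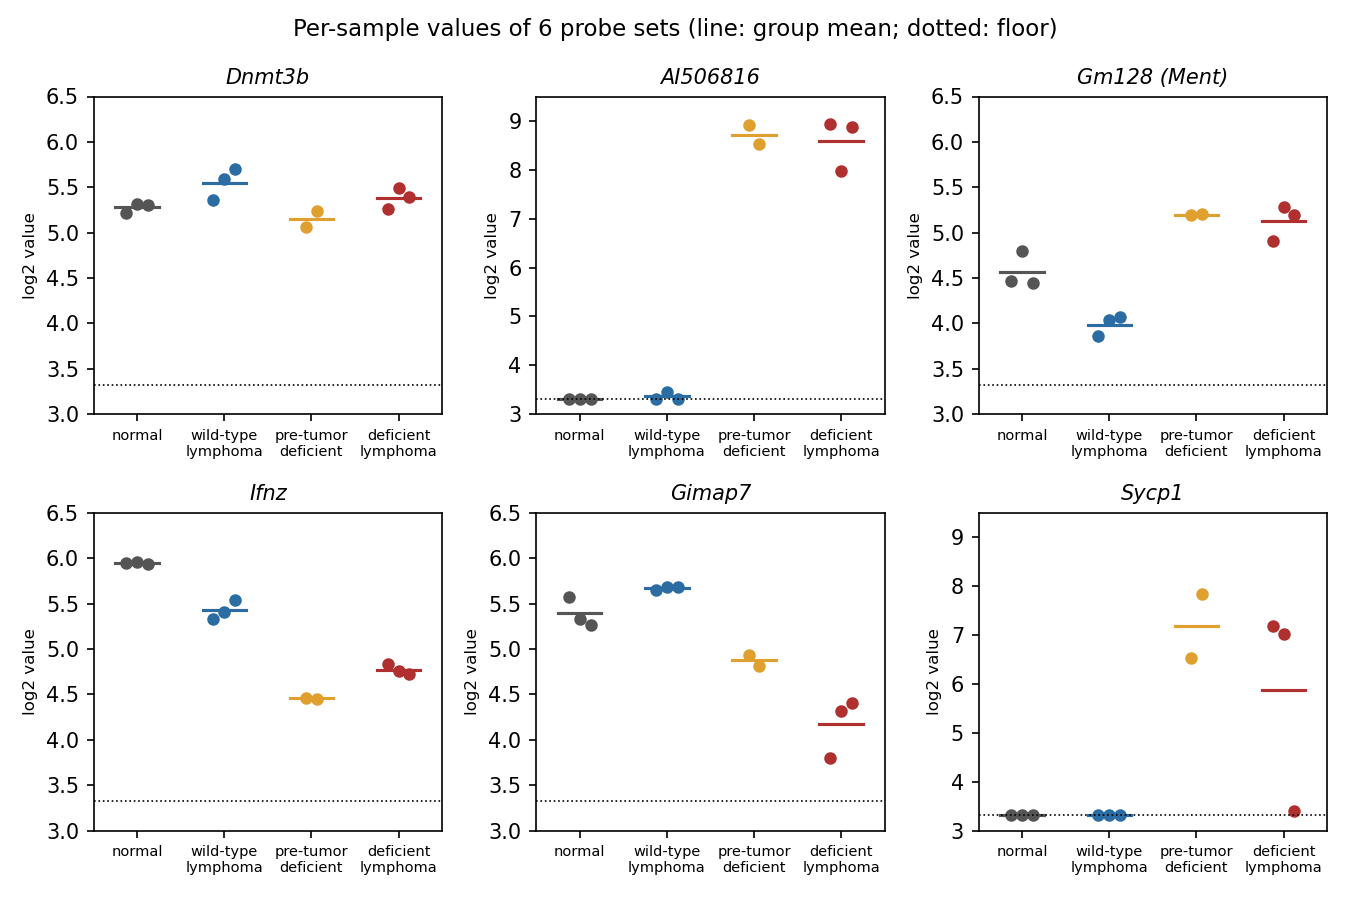
Log2 level of 6 genes in each of the 11 samples, by group; lines mark group means and the dotted line the floor at 3.32. AI506816 lies between 7.97 and 8.93 in the 5 Dnmt3b-deficient samples and between 3.32 and 3.45 in the other 6, while Dnmt3b lies between 5.07 and 5.70 throughout.

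Between the tumor genotypes, 1 gene rose and 1 fell in the Dnmt3b-deficient lymphomas. The probe set annotated AI506816, a gene known only by a sequence name, rose from 3.37 ± 0.08 in wild-type lymphomas, where 2 of 3 samples were at the floor, to 8.59 ± 0.54 (SD, n = 3 each), a difference of at least 5.22 (SE 0.25, adjusted p = 0.0017). Ifnz, a type I interferon gene, fell by 0.65 (SE 0.05), from 5.43 ± 0.11 to 4.77 ± 0.06 (adjusted p = 0.0360). Ment was higher in all 3 Dnmt3b-deficient lymphomas than in all 3 wild-type ones, by 1.14 (SE 0.13, 2.21-fold), and did not pass the adjustment (0.140). Gimap7, of a family of GTPases made in lymphocytes and chosen after its values were seen, was lower in all 3, by a difference of -1.50 (0.137). In total 2 of 28939 probe sets passed, and 1823 had an unadjusted p under 0.05; 2310 (7.98%) had no overlap between the groups, where chance gives 10% without ties. With the ties at the floor, the 10 splits of these 6 samples gave 6.72% on average, and 3 of them gave as large a share.

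These counts depended on single samples. Without wild-type replicates 1 and 3 there were 5 (2 up, 3 down) and 88 (19 up, 69 down) changed probe sets, and without Dnmt3b-deficient replicates 1, 2 and 3 there were 82 (75 up, 7 down), 9 (8 up, 1 down) and 20 (15 up, 5 down), so the prevailing direction depended on the sample left out. Without any one normal replicate there was 1, since every group enters the estimate of the spread. The counts were 8 without the dimmest probe sets and 7 without those at the floor, and 1 with a variance trend, without moderation, after quantile normalization or at a fold change of at least 2. AI506816 passed in 22 of 23 settings, with adjusted p between 5.39e-06 and 0.266, the highest with only the 2 groups compared. By probe set ID its 10 neighbours lie on chromosome 1, whereas RefSeq places AI506816 on chromosome 5, so the identity of the transcript is uncertain. Ifnz passed in 9 of 23 settings (0.0028 to 0.525), so this call is weak. It was lost without wild-type replicate 2 (0.103), Dnmt3b-deficient replicate 2 (0.0632), normal replicates 1, 2 or 3 (0.184, 0.135, 0.179) or either pre-tumor replicate (0.0915), and its size is below a fold change of 2. It was also lost with a trend (0.121), without moderation (0.0751), after quantile normalization (0.106), without the dimmest probe sets (0.0602) and with only the 2 groups (0.525). Ment passed in 4 of 23 (0.0116 to 0.525): without wild-type replicate 3 (0.0482), Dnmt3b-deficient replicate 1 (0.0116), the floor probe sets (0.0375) or the dimmest ones (0.0235). Gimap7 passed in 5 of 23 (0.0020 to 0.599): without wild-type replicate 3 (0.0494), Dnmt3b-deficient replicates 1 (0.0020) or 3 (0.0477), the floor probe sets (0.0354) or the dimmest ones (0.0101).

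Among genes with no overlap and an unadjusted p under 0.05, none of which passed the adjustment (0.226 to 0.789), the largest positive differences were in Sycp1 (at least 2.55) and Syce1 (2.46), which build the synaptonemal complex of meiosis. They were followed by Qser1 (2.40), the ephrin receptor Epha3 (1.92), the galectin Lgals1 (1.78), Tspan2 (1.72), the integrin Itgb7 (1.70), Mgst2 (1.68), the kinase Pkn3 (1.66) and Gsta4 (1.63). Sycp1 was at the floor in all wild-type lymphomas and at 7.19, 7.03 and 3.41 in the Dnmt3b-deficient ones. The largest negative differences were in the Wnt inhibitor Wif1 (-3.37), the amino acid transporter Slc7a8 (-2.46), the transcription factor Etv5 (-2.44), Chst2 (-2.34), complement factor Cfb (-2.27), Adamts3 (-2.21), Extl3 (-2.16), the activation marker Cd69 (-2.05), Rnf144b (-2.01) and Ms4a6c (-2.0). Leaving out wild-type replicate 3 brought Wif1 (adjusted p = 0.00759), Slc7a8 (0.00753), Adamts3 (0.0130), Extl3 (0.0028) and Rnf144b (0.000256) past the threshold. Leaving out Dnmt3b-deficient replicate 1 did the same for Syce1 (0.0145), Epha3 (0.0352) and Pkn3 (0.00778), replicate 3 of that group for Sycp1 (0.0307), and wild-type replicate 1 for Lgals1 (0.00543). Without the dimmest probe sets, Mgst2 passed (0.0254).

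At the level of gene lists, MYC and S phase genes were higher and T cell receptor and myeloid genes lower in the Dnmt3b-deficient lymphomas at the preset correlation. None of these 6 list calls held with an estimated correlation, where the lowest adjusted p was 0.321. No single one of the 410 list genes passed limma over all probe sets, and 58 had an unadjusted p under 0.05. Of 40 MYC-induced genes of ribosome biogenesis and metabolism, 37 had a positive difference (median 0.25, camera adjusted p = 7.15e-08), 11 had an unadjusted p under 0.05 and 1 rose when adjusted over the list alone, among them the RNA polymerase I subunit Polr1b (0.53). Of 31 S phase genes 27 were positive (median 0.15, 4.98e-05), 5 at an unadjusted p under 0.05, with 1 rise adjusted over the list alone; the replication licensing factor Cdt1 differed by 0.79. Both lists had adjusted p = 0.321 with an estimated correlation. Of 24 T cell receptor signalling genes 21 were negative (median -0.46, 7.42e-06), with Rasgrp1 at -1.76, Cd5 at -1.23 and Egr2 at -1.07, 5 at an unadjusted p under 0.05 and 0 past the threshold adjusted over the list alone. That call was lost at adjusted p = 0.448 with an estimated correlation.

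Markers of myeloid cells were lower as lists in the same tumors. Of 16 macrophage and monocyte genes 13 were negative (median -0.41, camera adjusted p = 4.07e-05), led by the lysozymes Lyz2 (-2.73) and Lyz1 (-2.25), and 1 fell adjusted over the list alone. The macrophage list mean was lower in wild-type replicate 3 (4.58) than in Dnmt3b-deficient replicate 2 (4.92). Of 13 dendritic cell genes 10 were negative (median -0.10, 0.00125), with the class II invariant chain Cd74 at -1.49 and H2-Aa at -1.24, and 2 fell adjusted over the list alone. The macrophage and dendritic cell lists both had adjusted p = 0.321 with an estimated correlation. Of 11 neutrophil genes 10 were negative (median -0.80, 0.00219), with Ngp at -1.34 and S100a8 at -1.32, and 0 passed adjusted over the list alone. The list mean was 6.09, 5.81 and 4.02 in wild-type and 3.99, 5.73 and 4.15 in Dnmt3b-deficient lymphomas, so wild-type replicate 3 and Dnmt3b-deficient replicate 2 each stood with the other genotype. This call had adjusted p = 0.592 with an estimated correlation and was lost without wild-type replicate 1 (0.290) or Dnmt3b-deficient replicates 1 (0.0877) and 3 (0.0992). The other 17 lists did not pass camera (0.0897 to 0.99), including germline genes (28 measured, 0.726) and stroma and endothelium (16 measured, 0.637). Adjusted over the list alone, 2 of 6 CDK inhibitors, 1 of 17 DNA methylation machinery genes and 1 of 15 double-positive genes fell. Of 19 mature single-positive genes 1 rose and 1 fell, and the remaining lists had 0.

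**Figure D2:**
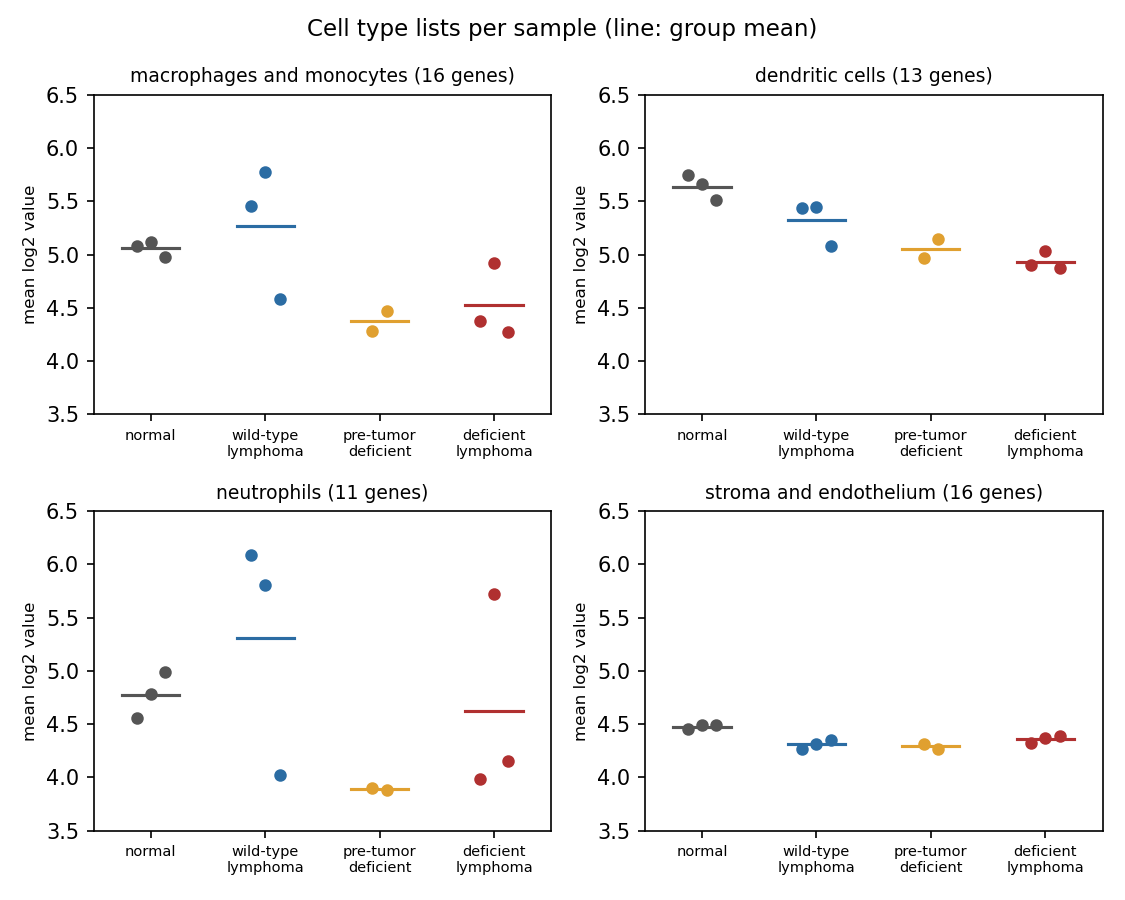
Mean log2 level of the macrophage, dendritic cell, neutrophil and stroma lists in each of the 11 samples, by group; lines mark group means. The macrophage list stands at 5.45, 5.78 and 4.58 in wild-type lymphomas and at 4.38, 4.92 and 4.27 in Dnmt3b-deficient ones, and the stroma list, at 4.26 to 4.49 over all samples, lies below the array medians of 4.55 to 4.62.

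Wild-type lymphomas had lower double-positive thymocyte genes and higher MYC-induced genes than normal thymocytes, list calls with adjusted p = 0.144 and adjusted p = 0.0590 with an estimated correlation. These groups differ at once in the MYC transgene, in the Cre transgene (carried by the normal mice), in stage and in time of harvest. Such differences cannot be told apart here. Terminal transferase Dntt fell from 9.71 ± 0.10 to 3.65 ± 0.30 and the recombinase gene Rag1 from 11.23 ± 0.19 to 5.25 ± 1.45 (SD, n = 3 each), differences of -6.06 and -5.98. The growth factor receptor adaptor Grb10 rose by 5.80 (from 4.15 to 9.95), Wif1 by 4.35, the metal-binding metallothionein Mt1 by 4.26 and asparagine synthetase Asns by 4.12. Further large rises were in the transferrin receptor Tfrc (3.84), the chaperones Hspd1 (3.64) and Hsp90aa1 (3.62), the pseudouridine synthase Dkc1 (3.60), the nuclear import factor Ipo7 (3.54) and Bcap29 (3.53). The falls included Glcci1 (-5.35), the lactate dehydrogenase subunit Ldhb (-4.78), cathepsin Ctsl (-4.75), H2-T10 (-4.74), the chromatin organizer Satb1 (-4.62), Plxnd1 (-4.50), Ephb6 (-4.47) and Ssbp2 (-4.29). Adjusted p-values of these 20 genes lay between 0.000216 (Ephb6) and 0.0277 (Ssbp2). Ssbp2 was the 1 gene of the 20 whose call was lost in any setting: without normal replicates 1, 2 or 3 (0.0726, 0.0755, 0.0711), without wild-type replicates 1 or 2 (0.0953, 0.0883), and with only the 2 groups compared (0.0834).

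In all, 5755 of 28939 probe sets changed, 2773 up and 2982 down, with 1964 genes higher and 2416 lower. Which direction had more depended on the scaling: 2953 up and 2554 down after centring the arrays on their medians, and 2770 and 3038 after quantile normalization. At a fold change of at least 2 the counts were 1446 up and 962 down (2408), and without wild-type replicate 1 a total of 3664 passed. Of the 410 list genes 139 changed, and 8 of the 23 lists passed camera. None of these 8 kept its call with an estimated correlation, where the lowest adjusted p was 0.0590.

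The double-positive, T cell receptor and Notch lists fell at the preset correlation. Of 15 double-positive thymocyte genes 12 fell (14 adjusted over the list alone; median -2.80, camera adjusted p = 2.13e-08), among them Dntt, Rag1, Satb1 and the cAMP-regulated phosphoprotein gene Arpp21 (-4.12); adjusted p = 0.144 with an estimated correlation. Of 24 T cell receptor signalling genes 11 fell (12 adjusted over the list alone; median -0.80, 0.00224), including the receptor chains Cd247 (-1.74) and Cd3e (-1.50), with adjusted p = 0.550 with an estimated correlation. In the Notch pathway, which drives early T cell fate, 4 of 17 genes fell (5 adjusted over the list alone; median -0.37, 0.0174): Notch1 (-2.52), the pre-T cell receptor chain Ptcra (-1.51), Notch3 (-1.40) and Maml1 (-1.38). That list had adjusted p = 0.388 with an estimated correlation. Early double-negative genes did not pass as a list (1 rose and 2 fell of 18, 0 and 2 adjusted over the list alone, camera 0.285), nor did mature single-positive genes (4 of 19 fell, also 4 adjusted over the list alone, 0.0806), where H2-Q2 (-2.96) and the homing receptor Ccr7 (-1.78) fell.

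The MYC, S phase and mitosis lists rose at the preset correlation. Of 40 MYC-induced genes 36 rose and none fell (37 adjusted over the list alone; median 1.14, camera adjusted p = 2.36e-27), including nucleophosmin Npm1 (3.48) and the snoRNP protein Nop58 (3.28); adjusted p = 0.0590 with an estimated correlation. In S phase, 8 of 31 genes rose and 1 fell (the same counts adjusted over the list alone; median 0.09, 0.00239), with the DNA polymerase subunits Pola1 (2.58) and Pole (1.43) and the helicase subunit Mcm6 (1.04) up. In mitosis, 9 of 24 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.42, 0.00341), including the checkpoint kinase Bub1 (2.61) and the spindle motor Kif11 (2.43). These lists had adjusted p = 0.449 and adjusted p = 0.559 with an estimated correlation. The cell cycle inhibitors Cdkn2d (-2.18) and Cdkn1b (-1.75) fell, 2 of 6 CDK inhibitors both over all probe sets and adjusted over the list alone, without a call for the list (0.131). Among p53 targets, Fas (-2.17) and the antiproliferative Btg2 (-2.05) fell and Ccng1 (2.05) rose, 3 of 17 (4 adjusted over the list alone, camera 0.824).

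The BCL2 family and interferon response lists fell at the preset correlation. Of 14 BCL2 family genes 6 fell and 1 rose (8 and 2 adjusted over the list alone; median -0.50, camera adjusted p = 0.00543): the antiapoptotic Bcl2l1 (-3.90) and the proapoptotic Bmf (-2.35) and Bcl2l11 (-1.80) were among the falls, so members with opposite known roles moved together. With an estimated correlation it had adjusted p = 0.388. Of 25 interferon response genes 14 fell and none rose (15 adjusted over the list alone; median -0.74, 4.93e-07), including Rtp4 (-2.89), the transcription factor Irf7 (-2.19), Zbp1 (-1.89) and Usp18 (-1.74), with adjusted p = 0.0674 with an estimated correlation. In the DNA methylation machinery 3 of 17 rose and 5 fell (5 and 6 adjusted over the list alone), with the chromatin remodeler Hells up by 2.86, the methyl-DNA binding Zbtb38 up by 1.03 and Gadd45a at -1.05; the list had no call (0.885), and its median (-0.17) and mean (0.05) differed in sign. Germline genes had 0 of 28 changed (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera 0.964). Of 23 imprinted genes 2 rose and 2 fell (the same adjusted over the list alone, 0.824), Grb10 and Impact (1.48) being the rises; the mean (0.15) was positive while the median (-0.05) and the test pointed down.

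Lists of other cell types did not pass camera in wild-type lymphomas. Macrophage genes went both ways (1 of 16 rose and 3 fell, as also adjusted over the list alone, 0.674), the integrin Itgam by 1.15 and the complement gene C1qa by -1.07. Thymic epithelium (2 of 13 fell, 0.132), dendritic cells (2 of 13 fell, 0.193), and NK and cytotoxic cells (1 of 14 rose and 1 fell, Nkg7 at -2.85, 0.885) had the same counts adjusted over the list alone. Erythroid cells had 2 of 6 fall (3 adjusted over the list alone, Car2 at -2.06, 0.151), and stroma and endothelium 3 of 16 (1 adjusted over the list alone, 0.209). B cells (12 measured, 0.679) and neutrophils (11 measured, 0.132) had 0 changed by limma over all and adjusted over the list alone, with 1 and 0 genes at an unadjusted p under 0.05.

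**Figure D3:**
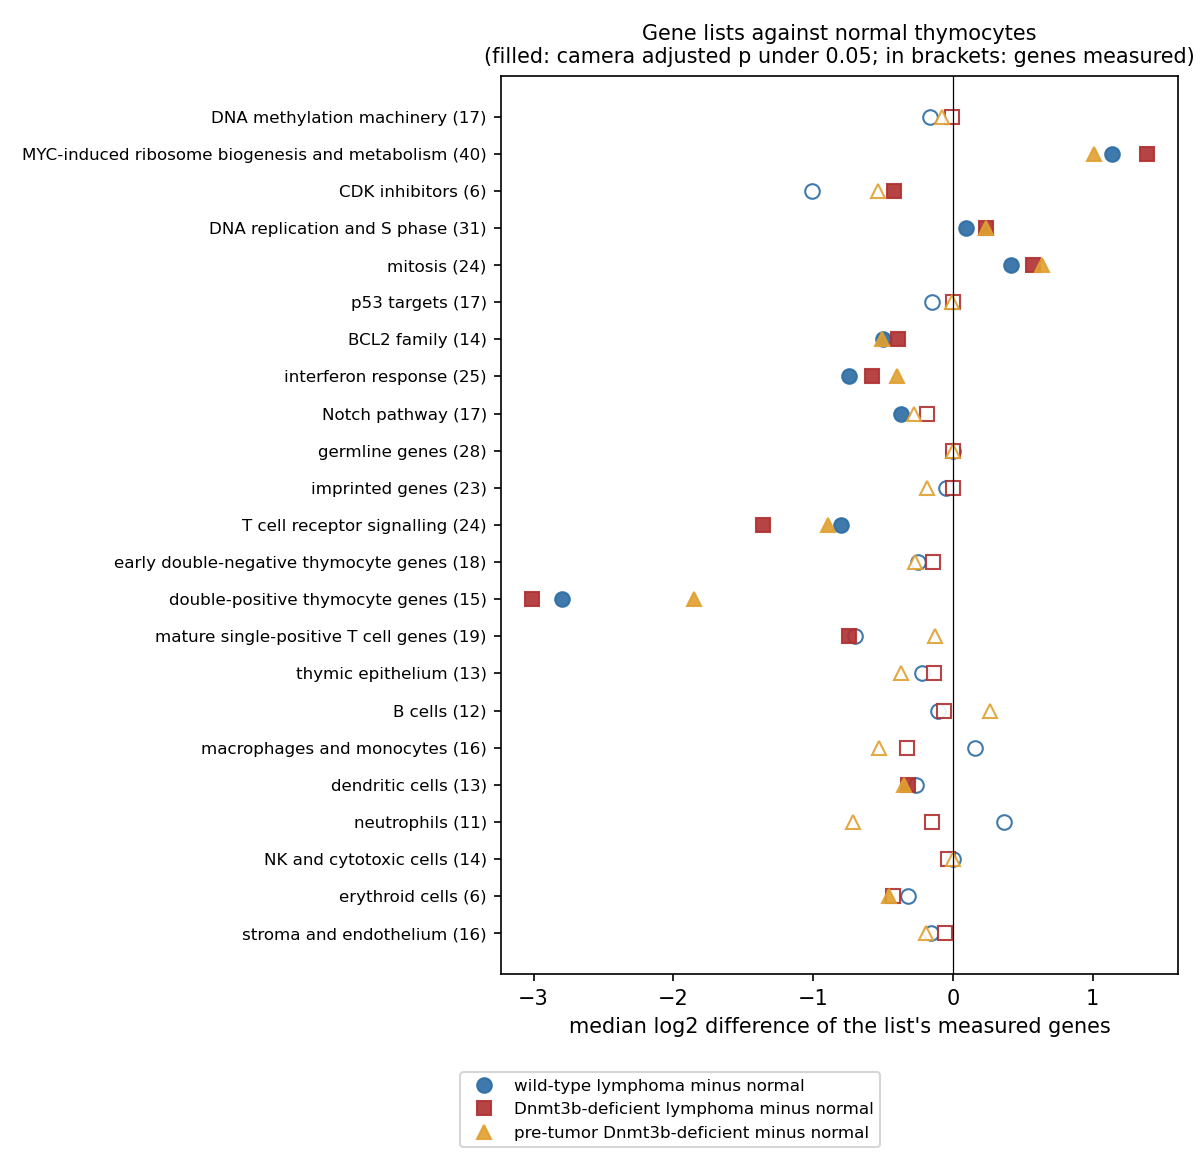
Median log2 difference from normal thymocytes of each of the 23 gene lists, in wild-type lymphomas, Dnmt3b-deficient lymphomas and pre-tumor Dnmt3b-deficient thymocytes; filled symbols passed camera at an adjusted p under 0.05, and brackets give the genes measured. The MYC list stands at 1.14, 1.39 and 1.01 and the double-positive list at -2.80, -3.01 and -1.86.

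Dnmt3b-deficient lymphomas differed from normal thymocytes through many of the same genes. Here the MYC transgene, Dnmt3b, stage and time of harvest differ at once and cannot be told apart. Mt1 rose from 5.40 ± 0.53 to 10.84 ± 0.52 (SD, n = 3 each; 5.44, adjusted p = 0.000149), Asns by 4.47, Hspd1 by 4.03, Dkc1 by 4.01, the cell cycle ubiquitin ligase Ccnb1ip1 by 3.92 and Hsp90aa1 by 3.86. The nuclear receptor gene Nr1h5, at the floor in all normal samples, was at least 13.6-fold higher (0.0237), and Mt2 (3.69), Npm1 (3.60) and Bcap29 (3.54) rose. The largest falls were Rag1 (-5.91, from 11.23 ± 0.19 to 5.32 ± 1.18), Glcci1 (-5.52), Dntt (-5.29), Ephb6 (-4.89, adjusted p = 9.95e-05), the thymus homing receptor Ccr9 (-4.64), Plxnd1 (-4.40), Ldhb (-4.37), Gpr162 (-4.06), Ctsl (-4.04) and the transcriptional repressor Bcl6 (-4.02). Nr1h5 was not called without normal replicates 1, 2 or 3 (0.0657, 0.0701, 0.0618) or Dnmt3b-deficient replicates 1 or 2 (0.0692, 0.0828), and Mt2 not without normal replicate 2 (0.0602) or with only the 2 groups compared (0.0795). In total 5860 probe sets changed, 2808 up and 3052 down (2020 and 2476 genes), 2815 and 2844 after centring, 2738 and 3128 after quantile normalization, and 1448 and 1084 (2532) at a fold change of at least 2.

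Of the 410 list genes 141 changed, and 10 lists passed camera. The MYC list was the 1 that held with an estimated correlation: 37 of 40 genes rose (38 adjusted over the list alone; median 1.39, camera adjusted p = 3.55e-29, adjusted p = 0.0493 with an estimated correlation), including the nucleolar proteins Nop58 (3.49) and nucleolin Ncl (3.46). In S phase 9 of 31 rose and none fell (11 adjusted over the list alone; median 0.24, 6.92e-07), with Pola1 (2.69), Pole (1.55), Mcm6 (1.27) and Mcm4 (1.19). Mitosis had 11 of 24 rise and 1 fall, also adjusted over the list alone (median 0.57, 0.00116), with Bub1 at 2.65. The 2 lists had adjusted p = 0.168 and adjusted p = 0.496 with an estimated correlation. Of 25 interferon response genes 13 fell (14 adjusted over the list alone; median -0.58, 9.93e-07), with Rtp4 (-2.71), Irf7 (-2.36), Zbp1 (-2.12) and Usp18 (-1.89), and adjusted p = 0.0830 with an estimated correlation. CDK inhibitors passed (2 of 6 fell, also adjusted over the list alone; median -0.42, 0.0389; Cdkn2d -2.46 and Cdkn1b -2.27), as did the BCL2 family (5 of 14 fell and 1 rose, 7 and 1 adjusted over the list alone; median -0.40, 0.0382; Bcl2l1 -3.85, Bmf -2.05, Bcl2 -1.46, Mcl1 -1.20). They had adjusted p = 0.300 and adjusted p = 0.460 with an estimated correlation. CDK inhibitors were lost without normal replicate 1 (0.119), Dnmt3b-deficient replicate 2 (0.0627), wild-type replicate 1 (0.0513), either pre-tumor replicate (0.0520), the dimmest probe sets (0.0616) or those at the floor (0.0513), and the BCL2 family without normal replicate 1 (0.0531), Dnmt3b-deficient replicates 2 (0.0627) or 3 (0.0705) or the dimmest probe sets (0.0570).

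The double-positive, T cell receptor and mature single-positive lists fell in the Dnmt3b-deficient lymphomas at the preset correlation. Of 15 double-positive genes 11 fell (14 adjusted over the list alone; median -3.01, camera adjusted p = 4.76e-09), and of 24 T cell receptor signalling genes 13 (18 adjusted over the list alone; median -1.36, 6.92e-07), including the kinase Itpkb (-2.09) and Cd247 (-1.85). These had adjusted p = 0.121 and adjusted p = 0.300 with an estimated correlation. Mature single-positive genes fell (7 of 19, 9 adjusted over the list alone; median -0.74, 0.0376; H2-Q2 -2.50 and the costimulatory receptor Tnfrsf4 -1.47), with adjusted p = 0.496 with an estimated correlation. That call was lost without normal replicates 1 (0.0683) or 3 (0.0593) or Dnmt3b-deficient replicate 1 (0.225). Dendritic cell genes fell beside them (5 of 13, also adjusted over the list alone; median -0.32, 0.00926), with the antigen presentation genes Cd74 (-2.12), H2-Aa (-1.93) and H2-Ab1 (-1.71), and adjusted p = 0.300 with an estimated correlation. Of the 13 lists that did not pass, the Notch pathway had 3 of 17 genes fall, the same adjusted over the list alone (Maml1 -1.44, Notch3 -1.18, Ptcra -1.17; 0.104).

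The 2 lymphoma comparisons shared 4764 calls in the same direction, 2329 up and 2435 down, where independent lists would share 269.1 and 314.5, and 1 call was opposite. Their differences correlated over probe sets with r = 0.897 and a covariance of 0.353. Both use the same 3 normal samples. In 20 simulations of unchanged groups, drawn around the means of those samples, the median was 0 shared calls, r = 0.0569 and a covariance of 0.00112. Groups drawn this way leave out the error of the normal means, so the simulation cannot show how much the shared controls add. Part of the excess over independent lists may come from the shared controls, since 3 normal samples are too few to split.

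Pre-tumor Dnmt3b-deficient thymocytes, at 24 days, had higher MYC-induced genes and lower double-positive thymocyte genes than normal thymocytes of the same age, list calls with adjusted p = 0.0713 and adjusted p = 0.392 with an estimated correlation. Mt1 rose from 5.40 ± 0.53 (SD, n = 3) to 10.57 ± 0.15 (n = 2), by 5.17 (adjusted p = 0.000921), Npm1 by 3.93, Hsp90aa1 by 3.92, Hspd1 by 3.90, Dkc1 by 3.78, Ipo7 by 3.75, Mt2 by 3.72 and the translation initiation factor Eif2s2 by 3.67. Nr1h5 and Sycp1, both at the floor in all normal samples, were at least 16.5-fold (0.0291) and at least 14.5-fold higher (0.0410). The falls were led by Usp17ld (-3.81), Ephb6 (-3.55), the retinol dehydrogenase family member Dhrs3 (-3.54), Slc16a5 (-3.30), Ly6d (-3.30), Plxnd1 (-3.22), Endou (-3.22), Gpr162 (-3.15), Glcci1 (-3.09) and Ldhb (-3.01). The groups differ in the MYC transgene and in Dnmt3b at once, and the pre-tumor cells were sorted.

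In total 5662 probe sets changed, 2804 up and 2858 down (1960 and 2315 genes), and 1669 and 817 (2486) at a fold change of at least 2. The near-even split became 3036 up and 2176 down after centring the arrays on their medians, and was 2768 and 2802 after quantile normalization. The count was 2250 with only the 2 groups compared (850 up, 1400 down) and 1712 without pre-tumor replicate 2. Without that replicate, Hsp90aa1 (0.0760), Eif2s2 (0.0960), Ly6d (0.0650), Endou (0.0528), Glcci1 (0.0718), Nr1h5 (0.202), Sycp1 (0.260), Mt2 (0.158) and Ldhb (0.240) were not called. The last 4 also missed the threshold without pre-tumor replicate 1 (0.0574, 0.0713, 0.0770 and 0.0760) and without normal replicates 1 (0.0676, 0.0880, 0.0552, 0.0853) or 2 (0.0760, 0.0987, 0.0786, 0.0923), and Nr1h5, Sycp1 and Ldhb without normal replicate 3 (0.0657, 0.0867, 0.0830). Sycp1 missed it without wild-type replicates 1, 2 or 3 too (0.0645, 0.0661, 0.0629), and Ldhb without wild-type replicate 1 (0.0526) or Dnmt3b-deficient replicate 3 (0.0571). With only the 2 groups compared, Hsp90aa1 (0.0919), Dkc1 (0.0513), Ipo7 (0.0732), Eif2s2 (0.0850), Plxnd1 (0.0509) and Glcci1 (0.115) were lost, and without moderation Sycp1 (0.0533) and Ldhb (0.0505).

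Of the 410 list genes 129 changed, and 9 lists passed camera, none of them with an estimated correlation. MYC-induced genes rose (33 of 40, 35 adjusted over the list alone; median 1.01, camera adjusted p = 1.62e-25, adjusted p = 0.0713 with an estimated correlation). S phase had 10 of 31 rise and 1 fall (11 and 1 adjusted over the list alone; median 0.23, 0.000113; Mcm4 1.41, Pole 1.31) and mitosis 12 of 24 rise and none fall (13 and 1 adjusted over the list alone; median 0.64, 2.79e-05). Falling lists were the BCL2 family (5 of 14 fell and 1 rose, 7 and 1 adjusted over the list alone; median -0.51, 0.0185; Bcl2l1 -2.78, Mcl1 -1.01) and double-positive genes (8 of 15, 9 adjusted over the list alone; median -1.86, 0.000665; Ets2 -2.19, the lipid antigen presenter Cd1d1 -1.86). These 4 lists had adjusted p = 0.392 with an estimated correlation. The interferon response fell (10 of 25 with 1 rise, 11 and 1 adjusted over the list alone; median -0.40, 0.00103; Zbp1 -1.69, Usp18 -1.64), with adjusted p = 0.371 with an estimated correlation. T cell receptor signalling fell (8 of 24, 12 adjusted over the list alone; median -0.89, 0.00146; the phospholipase Plcg1 -1.32), with adjusted p = 0.436 with an estimated correlation.

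Of the lists of other cell types, dendritic and erythroid markers passed in the sorted pre-tumor samples. Dendritic cell genes fell (7 of 13, also adjusted over the list alone; median -0.35, 0.0473), and erythroid genes too (2 of 6, 3 adjusted over the list alone; median -0.46, 0.0483; carbonic anhydrase Car2 -2.06), both with adjusted p = 0.392 with an estimated correlation. The dendritic call was lost without normal replicate 1 (0.115), pre-tumor replicate 1 (0.151), wild-type replicate 1 (0.0556) or Dnmt3b-deficient replicates 1 (0.0558) or 3 (0.0556). The erythroid call was lost without normal replicate 3 (0.0676), pre-tumor replicate 1 (0.123), the floor probe sets (0.0666), or any one lymphoma (0.0667, 0.0610 and 0.0703 for wild-type, 0.0664, 0.0601 and 0.0567 for Dnmt3b-deficient replicates). The macrophage list did not pass (0.181), with 3 of 16 genes down (also adjusted over the list alone), among them C1qc at -1.34. Nor did neutrophil genes (11 of 11 negative, 0 past the threshold, median -0.72, 0.405) or thymic epithelium (12 of 13 negative, 3 fell, also adjusted over the list alone, median -0.38, 0.0811). B cell genes tended the other way (7 of 12 positive, 1 rose, 0 adjusted over the list alone; median 0.27), without passing camera (0.0958).

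Both calls between the tumor genotypes recurred here, in the same direction. AI506816 was at the floor in all 3 normal samples and at 8.91 and 8.52 in the pre-tumor ones, at least 42.1-fold higher (adjusted p = 0.000426), and Ifnz fell by 1.49, from 5.95 to 4.45 (9.72e-05). Ifnz was also lower in wild-type lymphomas (5.33, 5.41 and 5.54) than in normal thymocytes (5.95, 5.96 and 5.93). A level below normal was thus not limited to Dnmt3b-deficient samples. Independent lists would share 0.0969 calls up and 0.0988 down, against the 1 and 1 observed. The comparisons use different samples but 1 estimate of the spread, so they are not independent lists, and fitted with only the 2 groups compared they shared 0 calls. Gimap7 differed by -0.52, which did not pass (0.0832) except with array weights (0.0404), without the dimmest probe sets (0.0458) or without Dnmt3b-deficient lymphoma replicate 1 (0.0134). The shared number was 1 without any one normal replicate and without pre-tumor replicate 2, 23 without wild-type replicate 3, and 13 and 7 without Dnmt3b-deficient replicates 1 and 3.

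Between pre-tumor thymocytes and lymphomas of the same Dnmt3b-deficient genotype, few single genes passed the threshold, with 2 and 3 samples. The kinase gene Rps6ka6 was at 6.29 ± 0.46 before tumors (SD, n = 2) and at the floor in all 3 lymphomas, at least 7.85-fold lower (adjusted p = 0.00116), and the steroid-metabolizing Akr1c18 was at least 6.85-fold lower (0.00476). Tcp11l2 (-1.23), Gstk1 (-1.06) and Zfp985 (-0.74, adjusted p = 6.76e-06) fell, and Mterf2, at the floor in all lymphomas, was at least 1.22-fold lower (5.64e-06). Znrd2 (0.76), Lmcd1 (0.64), Rpn1 (0.62), Fndc3b (0.57), the transcription factor Hand1 (0.46), the Fanconi anemia gene Fanca (0.38), Bgn (0.37) and Cox18 (0.25) rose, each less than a fold change of 2. In total 20 probe sets passed, 9 up and 11 down, of 2730 at an unadjusted p under 0.05. The split was 1 up and 14 down after centring the arrays on their medians, and 0 up and 9 down after quantile normalization.

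All these calls rest on the spread shared with the other groups: with only the 2 groups compared none of the named genes passed (0.0883 for Mterf2, 0.0899 for Zfp985, 0.241 for Rps6ka6, 0.273 for Akr1c18 and 0.182 to 0.431 for the others). Mterf2 also missed the threshold without the floor probe sets (0.120). Without pre-tumor replicate 2, Znrd2 (0.0954), Rpn1 (0.0738), Fndc3b (0.110), Fanca (0.0657), Bgn (0.119), Cox18 (0.116) and Gstk1 (0.0665) were lost. Without Dnmt3b-deficient replicate 3, Znrd2 (0.0776), Rpn1 (0.0906), Fndc3b (0.0756), Hand1 (0.0756), Bgn (0.0756), Tcp11l2 (0.0757) and Gstk1 (0.0531) were. Pre-tumor replicate 1 decided Znrd2 (0.0758), Rpn1 (0.0835), Fndc3b (0.0675) and Bgn (0.0556), and Dnmt3b-deficient replicate 2 Fndc3b (0.0662) and Hand1 (0.0507). Samples outside the comparison mattered through the shared spread: Znrd2, Rpn1, Bgn, Cox18, Hand1 and Tcp11l2 were lost without any one normal or wild-type lymphoma replicate (0.0540 to 0.108). Fanca was lost without normal replicates 1, 2 or 3 (0.0777, 0.0627, 0.0655) or wild-type replicate 3 (0.0592), and Fndc3b without normal replicates 1, 2 or 3 (0.107, 0.0958, 0.0926) or wild-type replicate 2 (0.0734). Gstk1 was lost without normal replicate 1 (0.0787) or wild-type replicates 1 (0.0538) or 3 (0.0592), and Lmcd1 without normal replicate 2 (0.0555) or wild-type replicate 3 (0.0569). After quantile normalization all 8 rises, Tcp11l2 and Gstk1 were not called (0.0521 to 0.425), and without the dimmest probe sets none of the 8 rises was (0.0552 to 0.336). Counts were 118 (97 up, 21 down), 51 (35 up, 16 down) and 30 (18 up, 12 down) without Dnmt3b-deficient replicates 1, 2 and 3, 114 (23 up, 91 down) and 52 (10 up, 42 down) without pre-tumor replicates 1 and 2, 8, 8 and 10 without normal replicates 1, 2 and 3, 13 and 8 without wild-type replicates 1 and 3, and 7 without moderation.

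As lists, double-positive, mature single-positive and T cell receptor genes stood lower in the lymphomas than before tumors, and MYC-induced genes higher, at the preset correlation. Early double-negative genes did not pass (10 of 18 positive, median 0.06, camera adjusted p = 0.657). None of the 7 list calls held with an estimated correlation, where the lowest adjusted p was 0.182. No list gene passed limma over all probe sets, and 80 of 410 had an unadjusted p under 0.05. All 15 double-positive genes were negative (7 fell adjusted over the list alone; median -1.27, camera adjusted p = 2.88e-11), among them Rag1 (-3.37), Dntt (-3.18), Ccr9 (-2.37) and Satb1 (-1.86). Dntt missed the threshold over all probe sets (0.0630) and passed without the floor probe sets (0.0272), without the dimmest ones (0.00862), without Dnmt3b-deficient replicate 1 (0.0466) and without pre-tumor replicate 2 (0.0465). Interferon response genes were lower too (3 fell adjusted over the list alone; median -0.12, 5.39e-05), and both lists had adjusted p = 0.182 with an estimated correlation. Mature single-positive genes (16 of 19 negative; median -0.64, 2.42e-06; 0 adjusted over the list alone) and B cell genes (1 of 12 fell adjusted over the list alone; median -0.40, 0.000814) were lower, and MYC-induced genes higher (33 of 40 positive, 11 rose adjusted over the list alone; median 0.23, 6.18e-07). These 3 lists had adjusted p = 0.279 with an estimated correlation. T cell receptor genes (median -0.33, 5.39e-05) and mitosis genes (median -0.21, 0.0129) were lower, with 0 members past the threshold adjusted over the list alone, and adjusted p = 0.522 and adjusted p = 0.675 with an estimated correlation. The B cell call was lost without pre-tumor replicate 1 (0.0559), the T cell receptor call without Dnmt3b-deficient replicate 1 (0.112), and the mitosis call without Dnmt3b-deficient replicate 3 (0.0788), while without pre-tumor replicate 2 its direction turned (0.316). Tumors were unsorted and pre-tumor cells sorted, so stage and sorting cannot be told apart here. Of the other cell types, neutrophil genes did not pass camera (11 of 11 positive, median 0.83, 0.227). Macrophage genes (14 of 16 positive, median 0.10, 0.587) and dendritic cell genes (8 of 13 negative, median -0.01, 0.383) did not pass either.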

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

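The tests on stroma genes, on the floxed allele and on the Cre transgene were chosen only after the results were seen. The values in this part were singled out because the tumor genotypes differed in them, except the last, a signal in probe sets that no comparison used. The 6 lymphomas allow 10 splits into 3 and 3, too few for a share under 0.05. Of these, 3 gave as many changed probe sets as the real 2, the highest other giving 16. That split set wild-type replicates 1 and 2 with Dnmt3b-deficient replicate 2 against the rest, which points to a structure of the samples apart from genotype. Neutrophil list means followed it (6.09, 5.81 and 5.73 against 4.02, 3.99 and 4.15). Macrophage list means did too (5.45, 5.78 and 4.92 against 4.58, 4.38 and 4.27). The dendritic cell list did not, with wild-type replicate 3 (5.08) above Dnmt3b-deficient replicate 2 (5.03). For lists, 4 splits gave as many as the real 6, the highest other being 7.

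AI506816 was higher by at least 5.22 in Dnmt3b-deficient than in wild-type lymphomas, of which 2 of 3 were at the floor, in 3 of 3 samples, and passed in 22 of 23 settings (adjusted p from 5.39e-06 to 0.266). The 10 nearest measured genes in RefSeq had a median difference of -0.00283 (-0.38 to 0.28), and the 10 nearest probe sets in ID order one of -0.0242 (-0.20 to 0.28). Neither set was raised, which argues against a segment that lifts its neighbours too, if the transcript lies at 1 of these places. A change limited to this transcript would leave its neighbours flat and stays open. A variant carried with the floxed allele is argued against by wild-type lymphomas, which carry that allele and on average lay 0.044 above the floor, and one carried with the Cre transgene by the difference of at least 5.40 between pre-tumor and normal thymocytes, since both carry Cre. Other differences between the mouse lines, which were not tested, and a link of this transcript to the loss of Dnmt3b stay open, the latter as a hypothesis. The transcript itself is uncertain, as the probe set's ID neighbours lie on another chromosome than the annotated gene.

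Macrophage, dendritic cell and neutrophil genes had median differences of -0.41, -0.10 and -0.80 between the tumor genotypes. At the preset correlation the macrophage list passed camera without each wild-type tumor (adjusted p = 0.00477, 0.000837 and 4.84e-08), but the neutrophil call was lost without wild-type replicate 1 (0.290). With an estimated correlation the macrophage call was lost with all tumors kept (0.321). The leave-out result is therefore only weak evidence against a single wild-type tumor rich in myeloid cells. More non-tumor cells of every kind in the wild-type tumors stays open, since 2 of the 16 stroma and endothelium genes, too few to decide, lay at least 1 above 4.58 there, the median of the tested probe sets over those arrays, and genes near the floor cannot show a fall. Over all settings the adjusted p ranged from 4.84e-08 to 0.321 for macrophages, 8.46e-05 to 0.321 for dendritic cells and 3.06e-09 to 0.592 for neutrophils, the highest with an estimated correlation. A lower myeloid share in some of the Dnmt3b-deficient tumors may account for the pattern, as may the timing of harvest, which was not tested. That share need not follow genotype: wild-type replicate 3 lay below Dnmt3b-deficient replicate 2 in the macrophage (4.58 and 4.92) and neutrophil lists (4.02 and 5.73).

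Ifnz differed by -0.65 between the tumor genotypes. MYC-induced genes had a median difference of 0.25, S phase genes of 0.15 and T cell receptor signalling genes of -0.46. Of the 6573 low-ID probe sets left out as probable controls, 671 (10.2%) changed between wild-type lymphoma and normal thymocytes, 326 up and 345 down, so that this block holds signal; the counts were 829 for Dnmt3b-deficient lymphoma and 802 for pre-tumor thymocytes against normal, 1 between the tumor genotypes and 3 between Dnmt3b-deficient lymphoma and pre-tumor thymocytes.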

How the results depend on the processing

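The alternatives without the floor probe sets and with the low-ID probe sets were chosen after seeing the data. Most named genes kept direction and side of the threshold: of the values recomputed for 305 results (a named gene counts once per comparison), 5958 did, 700 lost and 43 gained a call, and 3 turned; of those for 40 list calls, 564 were kept, 75 lost and 1 turned. Most losses came from leaving out 1 replicate (413 for genes), from fitting only the 2 groups compared (84) and, for lists, from the estimated correlation (39 of 40). The 413 is a sum over the 11 samples left out in turn, whereas the 84 comes from 1 setting. Other single settings with many losses for genes were a fold change of at least 2 (54) and the replicate block (47). Where a group is left with 1 sample, it is assumed to vary like the other groups. Array signal at the floor limits what can be read for dim genes. Replicate numbers did not pair the samples: 15 same-number pairs had a median correlation of -0.0914, and 30 others 0.0598.

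For the values below the cause was not tested, except that a stricter threshold lowers a count by construction. Samples of every group were left out for each comparison, since all enter the estimate of the spread. Changed probe sets between the tumor genotypes (2) were 1 with a trend, without moderation, after quantile normalization, at a fold change of at least 2 and with the replicate block (Ifnz at 0.278), 8 without the dimmest and 7 without the floor probe sets, and 1 to 88 without single replicates. With only the 2 groups compared the 2 calls were Ecscr and Rybp, none shared with those reported. Against normal thymocytes, the counts of 5755 for wild-type lymphoma, 5860 for Dnmt3b-deficient lymphoma and 5662 for pre-tumor thymocytes were 2408, 2532 and 2486 at a fold change of at least 2. Without that fold threshold, the pre-tumor count of 5662 was 2250 with only the 2 groups and 3269 with the block. Leaving out single replicates gave 3664 to 5707, 4270 to 5784 and 1712 to 5636. For Dnmt3b-deficient lymphoma against pre-tumor thymocytes (20) counts were 7 without moderation, 2 with only the 2 groups, 9 after quantile normalization, 8 at a fold change of at least 2, 4 with the block and 8 to 118 without single replicates. Calls shared by the tumor genotype and pre-tumor comparisons (2) were 1 with a trend, without moderation, after quantile normalization, at a fold change of at least 2 and with the block, 0 with only the 2 groups, 7 without the dimmest and 6 without the floor probe sets, and 1 to 23 without single replicates. Calls shared by both lymphomas were 1996 at a fold change of at least 2. With an estimated correlation, 0, 0, 1, 0 and 0 lists passed in the 5 comparisons, in place of 6, 8, 10, 9 and 7. Without single replicates, Dnmt3a between the tumor genotypes ranged from -0.38 to 0.31 (0.014 without Dnmt3b-deficient replicate 2), Gm128 between Dnmt3b-deficient lymphoma and pre-tumor thymocytes from -0.14 to 0.041, and the adjusted p of the mitosis list there from 5.43e-08 to 0.316, the last with the direction turned. The Dnmt3b difference between the tumor genotypes kept its sign (-0.26 to -0.089).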

Other observations

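The 5 Dnmt3b-deficient samples, tumor and pre-tumor, were also set against the 6 with intact Dnmt3b, a grouping not among the comparisons; the genes named from it were chosen after their values were seen. Apart from AI506816 (mean log2 level 8.64 against 3.34), the 5 lay above all 6 others for Qser1 (6.59 against 4.43), the RNA-binding Igf2bp3 (6.81 against 5.38), Mt1 (10.73 against 7.53) and Sycp1 (a difference of at least 3.07, the 6 others being at the floor). They lay below for the MAP kinase phosphatase Dusp6 (5.84 against 8.14), Extl3 (6.19 against 7.83), the T cell transcription factor Gata3 (7.77 against 8.92), Cd5 (a difference of -1.59), Gimap7 (-1.08) and Ifnz (4.65 against 5.69). The nearest samples of the 2 kinds were close for Sycp1, Cd5 and Gata3, with gaps of 0.08, 0.16 and 0.19. For Sycp1 the nearest was Dnmt3b-deficient lymphoma replicate 3, at 3.41. The gap was 4.51 for AI506816 and between 0.33 (Gimap7) and 0.74 (Qser1) for the other genes named. The 6 others pool normal thymocytes with wild-type lymphomas. Mt1 stood at 5.40 in the former and 9.66 in the latter, and Ifnz at 5.93 to 5.96 and at 5.33 to 5.54.

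In all, 261 probe sets separated the 2 kinds of sample (101 above, 160 below), 11 of them with a gap of at least 0.5 between the nearest samples. Over all possible splits of the 11 samples into 5 and 6, 27 separated as many (a share above 0.05, median 28 probe sets), so chance is not excluded. The highest other, 895, put all 3 normal samples with Dnmt3b-deficient replicates 1 and 3, which points to a structure of the samples. Part of it is the difference of normal thymocytes from each other group (5755, 5860 and 5662 changed probe sets). Splits that keep the normal samples together can separate many probe sets for that reason. The share of splits thus cannot measure chance for the grouping by Dnmt3b alone. A strain segment linked to the floxed Dnmt3b allele would also be present in the wild-type lymphomas, which carry that allele. It is therefore not expected to separate the 2 kinds of sample, and a count of neighbours can add little. Of the 198 separated genes, 0.505% lay among the 100 nearest to Dnmt3b (1 gene, upper 95% limit 2.78%), against 0.502% of all measured genes. Loss of Dnmt3b may account for single genes among the 261, as a hypothesis; other differences between the mouse lines stay open.

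For the lymphomas against normal thymocytes, 10 splits are too few for a share under 0.05: wild-type lymphoma gave 5755 changed probe sets (highest other split 3; 1 split as large, the real one) and 8 lists (highest other 6; 1 split as large), and Dnmt3b-deficient lymphoma 5860 probe sets (highest other 6; 1 split as large) and 10 lists (highest other 10; 3 splits as large).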
